A study of Bos taurus with 6 samples.

How the data were processed

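The series holds 6 Affymetrix Bovine Genome arrays, 1 PBS and 1 MDP array for each of 3 calves, made from 1.7 micrograms of total RNA after 4 hours of stimulation, per the labels. The deposited table holds an intensity for each of 24128 probe sets and each array on a linear scale. Data were collected with GCOS 1.1, per the series description in the labels, and the expression algorithm is not given in the sources used here. The trimmed mean of each array, with 2 percent removed at each end, was 499.9 within rounding, so that the deposited intensity values had been scaled to a common target. No detection calls were used here, and a low intensity has no stated background.

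Intensities were taken as log2(value + 56.4), the pseudocount being the 25th percentile of all values, and a fold change on this scale understates the change of dim probe sets. The range of array medians was 0.23 on the log2 scale, under the limit of 0.3 fixed beforehand, so the deposited scaling was kept. The 112 control probe sets were left out, and probe sets with a mean above the 25th percentile of the means were tested, 18012 in all. Of the probe sets, 13318 had 1 gene symbol, 86 several and 10724 none listed in the platform annotation. Symbols were updated by gene ID to the ARS-UCD2.0 annotation, which held 99.7 percent of them. No gene was named from a probe set with several symbols, and no coordinates were used.

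MDP was compared with PBS by limma 3.58.1 in R 4.3.3, using lmFit and eBayes with an intensity trend and the calf as a fixed block, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Replicates are separate animals. The calf numbers in the labels pair the arrays, because both arrays of a number come from the same animal. Deviations from the group means correlated at 0.290, 0.323 and 0.339 within calves 129, 150 and 151. The block was part of the design fixed before the data were examined, and the fit without it was an alternative. The response of calf 129 was set against that of calves 150 and 151 by an interaction term, and the calf means of 129 were set against those of 150 and 151, each with 1 residual degree of freedom.

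The 23 gene lists were fixed before the data were examined and all were tested, with 390 of their genes measured. They cover NF-κB targets, cytokines, chemokines, the NOD pathway, Toll-like receptors, T cell activation, the T cell receptor, γδ and αβ T cell markers, interferon response, cytotoxic genes, homing, quiescence, cell cycle, apoptosis, heat shock, oxidative phosphorylation, glycolysis, ribosomal proteins, and markers of monocytes, neutrophils, B cells, and erythrocytes and platelets. Each of 7756 genes was represented by its brightest probe set. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. None of the lists passed with an estimated correlation, and the smallest adjusted p of fry for a shift in one direction was 0.301.

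The genes named in the text follow a rule fixed beforehand. For MDP against PBS it takes the 12 largest increases and the 12 largest decreases among probe sets with 1 symbol that passed and moved the same way in all 3 calves. Where fewer passed, places were filled by the largest changes with an unadjusted p under 0.05, given as values. It adds up to 4 members of each list with the smallest p, the 8 largest differences per direction between calves, the 5 smallest p of the response difference, and NOD1, NOD2, RIPK2 and T cell receptor chains where measured. GADD45B, TRAF1, CXCL8, CXCL5, CCL4, IL1B, TNF, IFNG and S100A8 were named after their values were seen.

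The fits were tested on 20 simulated data sets of 18012 probe sets, with 100 changed by 1 and 100 by 0.5 on the log2 scale. For MDP against PBS 52.0 percent of the larger and 9.75 percent of the smaller changes were recovered with variances drawn from the fitted model, with 5.66 percent false calls, and 68.8 and 23.4 percent with each probe set's fitted variance, with 6.11 percent false calls. The fits with 1 residual degree of freedom exceeded the nominal rate. False calls were 48.8 and 16.2 percent for the response difference, and 56.4 and 38.0 percent for the calf means. With 1 calf left out the MDP comparison also has 1 residual degree of freedom, and false calls were between 11.0 and 25.2 percent, so that calls gained there are less certain. Lists with 1 calf left out were not simulated. Their estimated prior degrees of freedom rest on a single residual degree of freedom. For gene lists, 7756 genes were simulated with the 20 of the NF-κB list shifted by 0.5, and that list was called in 100 percent of 20 simulations, and other lists in 0.238 percent of tests. The simulated genes varied independently, while the estimated correlation in the NF-κB list was 0.54. These simulations therefore do not give the false-call rate of the list test for correlated genes. Alternatives were other pseudocounts, normalizations, filters, variance models, the block, the choice of probe sets, and leaving out each calf. Figures were drawn with matplotlib 3.10.9.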

Results

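Gene expression was measured on Affymetrix Bovine Genome arrays in γδ T cells from the blood of 3 calves, numbered 129, 150 and 151. The cells of each calf were kept for 4 hours with muramyl dipeptide (MDP), a fragment of bacterial peptidoglycan that the intracellular receptor NOD2 senses, or with phosphate-buffered saline (PBS). This gave 3 MDP and 3 PBS arrays, with 1 of each per calf. GD3.8, an antibody to the γδ T cell receptor, was used for all sorts, with a cell sorter for calf 129 and magnetic beads for calves 150 and 151. The labels give a purity above 98 percent for the bead-sorted cells. The protocol of the calf 129 MDP sample leaves out the overnight rest that the protocols of the other 5 samples state, while the series description gives the rest for all. Median signal per array lay between 155.2 and 192.6, and the number of arrays limits the precision of every comparison.

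In the fit with the calf as a block, genes of NF-κB signalling and of T cell activation were higher with MDP, while 0 probe sets passed without the block. Of 18012 probe sets tested, 59 rose, naming 36 genes, and 9 fell, naming 5 genes (limma with the calf as a block, Benjamini-Hochberg adjustment). All 68 moved the same way in 3 of 3 calves, but the test that picked them used these same calves and favours such probe sets. Over all tested probe sets the changes correlated at 0.081 between calves 129 and 150. The correlation was 0.055 between calves 129 and 151, and 0.029 between calves 150 and 151. The largest rise was that of TNFRSF18 (GITR, a costimulatory receptor of T cells), by 1.75 ± 0.29 (SE, n = 3 pairs) on the log2 scale or 3.37-fold (adjusted p = 0.0121). Each SE here and below is the moderated one of limma, which borrows variance from other probe sets and is not the spread between calves. The SD of the 3 calf changes was 1.28 for TNFRSF18, and 0.037 for the PELI1 probe set named below with 1.06. SEMA4A rose by 1.47 ± 0.17 (adjusted p = 0.000731) and RGS1, a brake on signalling through G protein-coupled receptors, by 1.35 ± 0.16. TRAF4 rose by 1.29 ± 0.23, RGN by 1.26 ± 0.20 and MARCKS by 1.14 ± 0.16. PELI1, a ubiquitin ligase of innate receptor signalling, rose by 1.06 ± 0.21, and NCF1, a subunit of the phagocyte NADPH oxidase, by 1.04 ± 0.16. The other probe sets of PELI1 had 0.75 (adjusted p = 0.00273) and 0.70 (adjusted p = 0.127).

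**Figure D1:**
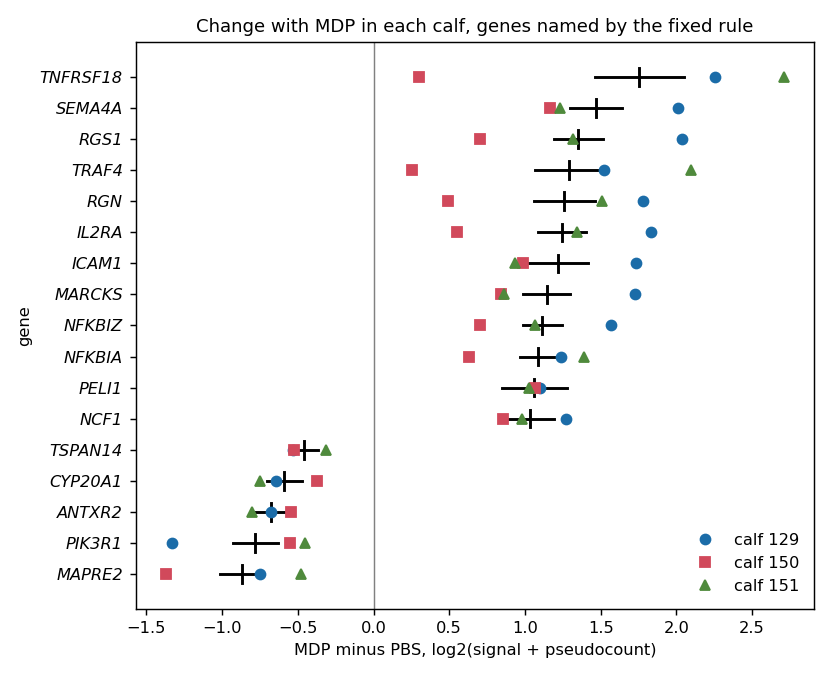
Change with MDP in each calf (MDP minus PBS, on the log2 scale) for the genes named by the fixed rule that passed the test. Points are calves and the vertical bar is the mean. The horizontal bar is the moderated standard error of limma, which borrows variance from other probe sets and is not the spread of the points. TNFRSF18 had the largest mean rise, 1.75, with 0.30 in calf 150, and MAPRE2 the largest fall, -0.87.

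Of the 20 measured genes of the NF-κB target list, 6 rose and 14 did not pass over all probe sets, and 15 were higher when adjusted over the list alone. All 20 had a positive mean change, and the list mean was 0.57. NFKBIA, the inhibitor that NF-κB itself induces, rose by 1.08 ± 0.12, from signals of 7385, 9485 and 4683 with PBS to 17457, 14682 and 12355 with MDP in calves 129, 150 and 151. NFKBIZ rose by 1.12 ± 0.13, the adhesion molecule ICAM1 by 1.22 ± 0.20 and NFKB2 by 0.88 ± 0.14, and GADD45B (0.72 ± 0.13) and TRAF1 (0.96 ± 0.18) were the other two, TRAF1 with 0.55 without calf 129. A second probe set of NFKBIZ had a mean change of 0.19 (adjusted p = 0.881). The list passed in camera with a preset correlation (adjusted p = 4.29e-26) and not with an estimated one (adjusted p = 0.536 with an estimated correlation).

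Genes of T cell activation and early response rose in 4 of 23 measured members, while 19 did not pass and 6 passed adjusted over the list alone. They were TNFRSF18, the transcription factor JUNB (0.82 ± 0.09), IL2RA, the high-affinity chain of the interleukin-2 receptor (1.24 ± 0.16), and the early activation marker CD69 (1.03 ± 0.14). The list mean was 0.26 (camera adjusted p = 1.50e-05, and adjusted p = 0.536 with an estimated correlation), and without calf 129 it was 0.13. In calf 150, CD69 already had a PBS signal of 2489, against 856 in calf 129 and 419 in calf 151.

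Among the 17 measured apoptosis genes FAS rose, by 1.03 ± 0.17, and BCL2A1 (0.54), CASP6 (0.37) and MCL1 (0.37) passed adjusted over the list alone, as did FAS, which makes 4. BCL2A1 had 0.33 without calf 129 and MCL1 0.23 without calf 151. The list mean was 0.18 (camera adjusted p = 0.0214, and adjusted p = 0.536 with an estimated correlation), and without calf 129 it was 0.12. No cytokine of 24 passed over all probe sets. Adjusted over the list alone 3 passed, namely the interleukin-1 antagonist IL1RN (0.56), CSF2 (1.19) and LTB (0.33), while LTA had 0.83 (adjusted p = 0.378 over all probe sets), with 1.36 without calf 150 and 0.33 without calf 151. CSF2 had changes of 2.47, 1.12 and -0.026 in calves 129, 150 and 151. Without calf 129, IL1RN had 0.36, CSF2 0.55 and LTB 0.21, and without calf 151 CSF2 had 1.79. The cytokine list mean was 0.18 (camera adjusted p = 0.0216, and adjusted p = 0.651 with an estimated correlation), and without calf 129 it was 0.04.

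None of 14 measured chemokines passed over all probe sets. Adjusted over the list alone 6 did, 4 of them higher, with CXCL16 at 0.60, CCL3 at 0.53 and CCL20 at 0.75, and 2 lower, with CXCL12 at -0.80. Without calf 129 these 4 had 0.38, 0.33, 0.43 and -0.53. The list mean was 0.05 and its median -0.01 (camera adjusted p = 0.458), and without calf 150 the list passed, at 0.15. CXCL8, CXCL5, CCL4 and IL1B, named after their values were seen, had changes of -0.06, -0.06, -0.03 and 0.18, none of them past the threshold. TNF had 0.49 (adjusted p = 0.589) and IFNG 0.35 (adjusted p = 0.866), at low signals.

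In the NOD pathway and inflammasome list 1 of 17 measured genes rose, the kinase IKBKB, by 0.64 ± 0.13 (list mean 0.08, and 0.03 without calf 129, camera adjusted p = 0.125), and 3 passed adjusted over the list alone, among them TAB2 (0.40) and HSP90AA1 (0.29, and 0.16 without calf 129). RIPK2, the kinase that NOD2 recruits, had a change of 0.30 ± 0.12 (adjusted p = 0.457). NOD1 and NOD2 were not analysed here, as no probe set was named for them. No member of the 13 Toll-like receptor and adaptor genes passed, with CD14 at -0.33, TLR9 at 0.38, TRAF3 at 0.29 and TLR2 at 0.13 (list mean 0.09, camera adjusted p = 0.498).

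Of the 5 named genes that fell, the microtubule-binding MAPRE2 fell by 0.87 ± 0.14 (adjusted p = 0.0118), and PIK3R1, a regulatory subunit of phosphoinositide 3-kinase, fell by 0.78 ± 0.15 (adjusted p = 0.0319). ANTXR2 fell by 0.67 ± 0.13, CYP20A1 fell by 0.59 ± 0.12 and TSPAN14 fell by 0.46 ± 0.09. No other probe set of these genes passed, with -0.33 for MAPRE2 (adjusted p = 0.693), -0.26, -0.44 and -0.34 for the 3 of ANTXR2 (adjusted p = 0.608, 0.268 and 0.341) and -0.29 for CYP20A1 (adjusted p = 0.501). PIK3R1 had -0.50 without calf 129. Without the filter no fall passed, as all 20 calls there were higher with MDP, while 12 probe sets passed as lower with the filter at the median. The 7 further genes with the largest mean decreases among those under an unadjusted p of 0.05 did not pass: DBN1 (-1.38, adjusted p = 0.0539), MTG1 (-1.25), BCAM (-1.21), ASPHD1 (-1.21), CCNT1 (-1.17), ACTN3 (-1.15) and CLDN19 (-1.14). Their signals with MDP were low, at most 102.6, and ASPHD1 had -0.70 without calf 151. One of 3 other probe sets of MTG1 had a change of opposite sign, 0.11.

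Genes of the T cell receptor did not pass. CD3D had 0.06, CD3E 0.10, CD3G -0.06 and CD247 -0.12, none past the threshold, and TARP, from the T cell receptor γ locus, had -0.34 (adjusted p = 0.442). In the T cell receptor complex and signalling list none of 21 passed and PLCG1 (-0.40) passed adjusted over the list alone, beside CD5 (0.38) and LAT (-0.27) that did not (list mean -0.04, camera adjusted p = 0.235). All 5 measured γδ T cell and WC1 markers had negative mean changes (list mean -0.25, camera adjusted p = 0.0172, and adjusted p = 0.536 with an estimated correlation). ID3 (-0.43, and -0.28 without calf 129) alone passed over that list, and BLK and ZBTB16 had -0.07 and -0.33. The list mean was -0.08 without calf 129 and -0.40 without calf 150. αβ T cell markers had a mean of 0.24 (camera adjusted p = 0.0757). CD5, which is also in the T cell receptor list, passed over the αβ list alone, and TCRA (0.44), CD4 (0.35) and CD8B (0.16) did not. The αβ list mean was 0.34 without calf 129, where the list passed, and 0.16 without calf 150. TCRA was represented by the brightest of its 24 probe sets, and the others are not given here. That probe set had changes of -0.30, 1.28 and 0.34 in calves 129, 150 and 151. It had 0.81 and passed without calf 129, and had 0.021 without calf 150. CD4 had 0.015 without calf 151.

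No list of markers of other cell types passed as higher with MDP. All 7 measured neutrophil markers had negative mean changes (list mean -0.26, camera adjusted p = 0.00838, and adjusted p = 0.536 with an estimated correlation), among them MMP9 (-0.34, which passed over the list alone and was -0.22 without calf 150), S100A12 (-0.21), S100A9 (-0.29) and CXCR1 (-0.51). The mean of 13 monocyte and macrophage markers was -0.14 (camera adjusted p = 0.143), with CYBB at 0.41, VCAN at -0.39 and TYROBP at -0.28. B cell and MHC class II genes had a mean of -0.16 (camera adjusted p = 0.138), with BOLA-DQA1 at -0.54, FCER2 at -0.49, CD79A at -0.25 and BOLA-DMB at -0.69. Of these, FCER2 had -0.88 without calf 150, BOLA-DMB -0.054 without calf 151 and CD79A 0.026 without calf 129. Among 7 erythrocyte and platelet markers the integrin ITGB3 rose, by 0.53 ± 0.11, while GYPC (-0.24), HBM (-0.45) and HBB (-0.40) did not pass (list mean -0.05, camera adjusted p = 0.934). The 3 dimmer probe sets of ITGB3 had -0.16, 0.12 and 0.22 and did not pass. As to RNA quality, the 3' to 5' signal ratio of the actin control ranged from 2.26 to 18.7 between arrays, and was lower with MDP in calf 129 and higher in calves 150 and 151.

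**Figure D2:**
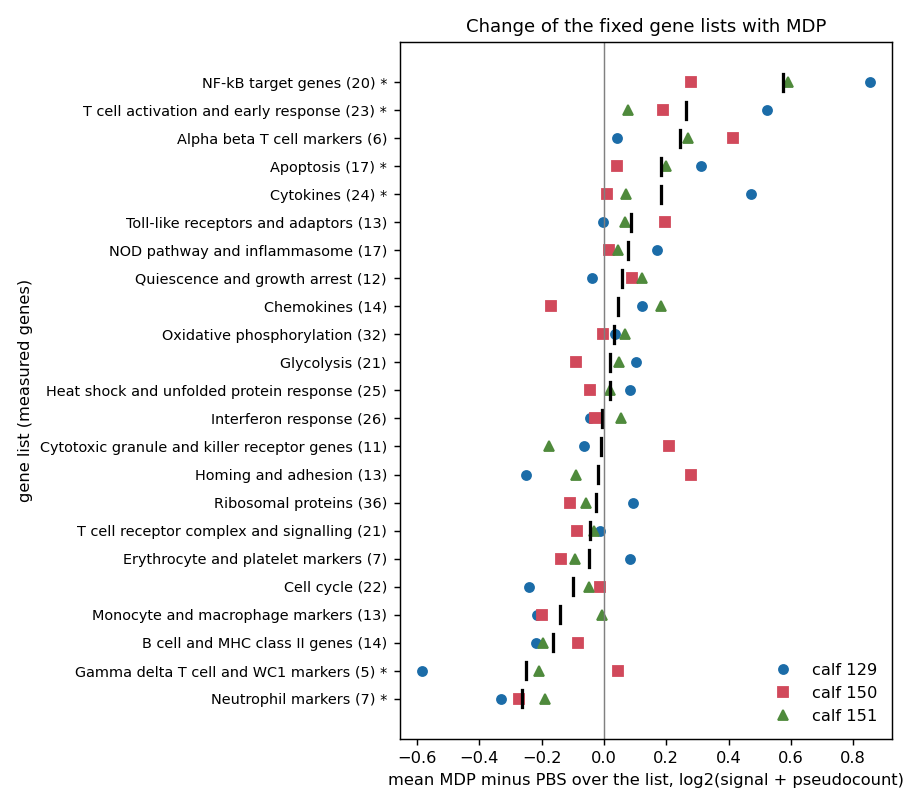
Mean change with MDP (MDP minus PBS, on the log2 scale) over the measured genes of each fixed list, whose number is in brackets; points are calves, the black bar is their mean, and a star marks lists past the threshold in camera with the preset correlation. NF-κB target genes had the highest mean, 0.57, and neutrophil markers the lowest, -0.26.

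No gene of the remaining lists passed over all probe sets, and none of these lists passed in camera. Adjusted over the list alone, 3 of 12 quiescence genes passed, CDKN1A (1.07, and 0.46 without calf 150), TOB1 (-0.34) and BTG1 (0.27, and 0.16 without calf 129), with KLF13 at -0.24 (list mean 0.06, camera adjusted p = 0.899). Among 13 homing and adhesion genes 2 did, SELPLG (-0.48) and S1PR1 (-0.36), with CXCR4 at 0.22 and ITGA4 at -0.48 (list mean -0.02, camera adjusted p = 0.274). Interferon response genes had a mean of -0.01 and a median of 0.04 (camera adjusted p = 0.899), with OAS1X at -0.57, RSAD2 at -0.30, GBP1 at 0.25 and IFI6 at 0.40. Cytotoxic granule genes had a mean of -0.01 and a median of 0.06 (camera adjusted p = 0.661), with PRF1 at -0.40, CTSW at -0.46, NKG7 at -0.38 and FASLG at 0.42. Cell cycle genes had a mean of -0.10 (adjusted p = 0.597), with MCM7 at 0.23, MCM6 at 0.20, BIRC5 at -0.66 and CDC20 at -0.51. Heat shock genes had a mean of 0.02 (adjusted p = 0.210), with HSPA5 at 0.34, HSP90AA1 at 0.29, HSP90B1 at 0.26 and HSPB1 at -0.28. Glycolysis genes had 0.02 (adjusted p = 0.899), with HIF1A at 0.29, GAPDH at -0.23, PKM at -0.19 and ALDOA at 0.11. Oxidative phosphorylation genes had 0.03 (adjusted p = 0.320), with UQCRQ at -0.36, NDUFV2 at 0.18, NDUFC1 at 0.20 and COX7A2 at 0.19. Ribosomal protein genes had -0.02 (adjusted p = 0.318), with RPS28 at 0.15, RPL35 at -0.12, RPS27 at -0.10 and RPS20 at -0.09, and the list turned sign under quantile normalization (0.01) and passed without calf 129 (-0.08).

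The 68 calls rest on the calf block and on the variance model, since 0 probe sets passed in limma without the block (639 at an unadjusted p under 0.05), 0 with the calf as a random block (1361), 0 without the intensity trend (1214), 20 without the filter and 44 with robust variances, under which TNFRSF18, RGS1, TRAF4, IL2RA, TRAF1, TSPAN14, ITGB3 and IKBKB did not pass. The count was 139 without calf 129 and 115 without calf 150, in fits with 1 residual degree of freedom that gave up to 25.2 percent false calls on simulated data, so these counts cannot be set against the 68 as more changes. MAPRE2, PELI1 and TSPAN14 did not pass without calf 150, nor ANTXR2, CYP20A1, TSPAN14, ITGB3 and IKBKB without calf 151. PIK3R1, ANTXR2, CYP20A1, TRAF1, ITGB3 and IKBKB did not pass under quantile normalization. Of the lists 1 passed without the block, and 3 of the 20 still tested passed with the filter at the median. The lists of apoptosis, cytokines and γδ markers did not pass without calf 129, nor neutrophil markers without calf 150. Of the genes and lists followed through the alternatives that did not pass, 59 of 91 genes and 15 of 17 lists moved by over 1.5 times or turned sign when 1 calf was left out.

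The response of calf 129 was set against that of calves 150 and 151, as the labels give the sort method and the animal. In limma with 1 residual degree of freedom and a single calf on one side, 65 probe sets passed, 38 with a higher and 27 with a lower response in calf 129. The chemokine receptor gene CCR4 had a change of 1.87 in calf 129 against 0.31 and 0.34 in calves 150 and 151 (difference 1.54 ± 0.22 SE). RGS1 had 2.04 against 0.71 and 1.32 (difference 1.03 ± 0.16). The estimated prior degrees of freedom of this fit were infinite, so each SE here comes from the intensity trend of the variance alone. The spread of the probe set itself, such as that of RGS1 between calves 150 and 151, has no weight in its SE. The difference was -0.99 for MYH7, and -1.14 and 0.997 for 2 probe sets with no symbol listed. On simulated data this fit gave 48.8 or 16.2 percent false calls, depending on how variances were drawn, and 0 probe sets passed with the prior variance of the MDP comparison (1030 at an unadjusted p under 0.05, an alternative chosen after seeing the data). The count was also 28 under quantile normalization, 17 with array medians set equal, 1 without the filter and 0 without the intensity trend (948), and sort method, handling and animal cannot be told apart.

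Between animals, the MHC class II genes BOLA-DQB1, BOLA-DQA5 and BOLA-DRB3 were among those that passed as higher in calf 129 than in calves 150 and 151. Of the 15 probe sets that passed on calf means, 10 were higher, naming 6 genes, and 5 lower, naming 1 gene. BOLA-DQB1 (adjusted p = 0.0008) had signals of 1503 and 2109 in calf 129 and at most 8.5 in the others, and BOLA-DQA5 (adjusted p = 0.00836) had 999.7 and 1362 against at most 80.7. No size is given for these differences, because it follows the pseudocount where signals are not shown to lie above background. The probe set named BoLA was higher by 2.51 ± 0.24 (SE, 1 calf against 2) and BOLA-DRB3 by 1.86 ± 0.25. S100A13 (2.20 ± 0.27) and ENPP1 (1.45 ± 0.20) were also higher, and MTSS1 had -1.72 ± 0.20. B cell and MHC class II genes as a list passed as higher, by 0.48 (camera adjusted p = 0.00071, and 0.31 without calf 150), and ribosomal protein genes lower, at -0.14 (camera adjusted p = 0.00146), neither with an estimated correlation (adjusted p = 0.871 with an estimated correlation for both). Of the 14 measured genes of the first list BOLA-DRB3 alone passed, and BOLA-DQA1 had -0.42. On simulated data this fit gave 56.4 or 38.0 percent false calls. One side is a single calf with no spread of its own, so these differences are not established, and sort method and animal cannot be told apart. The count was 8 under quantile normalization, 100 with array medians set equal, 2 without the intensity trend and 0 on the MDP arrays alone (960 at an unadjusted p under 0.05 in limma), and the ribosomal list turned sign under quantile normalization (0.0014).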

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

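The tests of array scaling, RNA quality, myeloid cells and the size of the calf 129 response were chosen after the results were seen, and the counts of splits were planned. In the interaction test of the response of calf 129 against that of calves 150 and 151, 65 probe sets passed. CCR4 (1.54), RGS1 (1.03), IL2RA (0.88), TRAF1 (1.22), CSF2 (1.92), IL1B (0.75) and a probe set with no symbol listed (0.997) had the higher response in calf 129, and MYH7 (-0.99), CD79A (-0.82) and another unnamed probe set (-1.14) the lower. One side of this test is a single calf, which gives no spread of its own, so a difference in response is not established. The calls are also limited by the false calls of this fit on simulated data and by the count of 0 with the prior variance of the MDP comparison.

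The response in calf 129 was larger for NF-κB targets, with a list change of 0.85 against 0.28 in calf 150 and 0.59 in calf 151, a difference of 0.42 from the mean of those 2. Calves 151 and 150, sorted by the same method, themselves differed by 0.31, so calf 129 does not stand clearly apart. Wider changes across the whole array pair as the whole cause are argued against. The SD of all log2 changes in calf 129 was 0.932 times that in calf 151 and 1.14 times that in calf 150, while its NF-κB list change was 1.44 and 3.05 times theirs, and a smaller part against calf 150 stays open. Sort method, the rest in the label of the MDP sample, and the animal cannot be told apart, since 1 animal was sorted by the cell sorter. The NF-κB list had its highest PBS level in calf 150 for 15 of 20 genes. Of the 59 probe sets that rose with MDP, calf 150 had the highest PBS level in 54 and the smallest change in 49. Both counts use the same PBS values, so they are not independent.

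The rise of NF-κB and activation genes with MDP was set against technical explanations. Under quantile normalization and equal medians the lowest NF-κB list change in any calf was 0.26, which argues against array scaling. The 3' to 5' ratio moved the same way in all 3 calves for 0 of 3 control transcripts, so no shift of RNA quality common to the calves was seen. The log2 actin ratio changed by -1.30, 0.97 and 1.17 in calves 129, 150 and 151. With this spread over 3 calves the ratios cannot decide on RNA quality, which stays open. The monocyte and neutrophil markers together had a mean change of -0.070 in the calf where it was highest. This argues against a larger share of these cells with MDP only as far as MDP left the markers themselves unchanged, which was not tested. Monocytes or neutrophils present in both samples may have responded, and this stays open, since CXCL8 and IL1B had a mean change of 0.46 in calf 129, -0.31 in calf 150 and 0.035 in calf 151, which had the highest myeloid marker level, and 2 genes are too few to decide.

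Of the 10 splits of the 6 arrays into 3 and 3, with the calf block kept, 1 gave as many calls as the real one, which is the real split itself with 68, and the highest other count was 0. For gene lists 4 of the 10 splits gave at least as many as the real 6, and the highest other count was 7. Only 4 of the splits part all 3 pairs, as the real one does. The rest part 1 pair, so that with the block they compare MDP with PBS in that calf alone. They hold the treatment itself and their counts repeat, and the 7 lists are those of calf 129. The share over the 10 splits can never be under 0.1 and mixes both kinds, so it does not measure chance. Among the 4 splits that part all 3 pairs the highest other counts were 0 calls and 6 lists. These splits are too few to say whether chance is excluded.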

How the results depend on the processing

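The robust variances and the prior variance of the MDP comparison were chosen after seeing the data, and the other alternatives before the data were examined. For MDP against PBS all 68 called probe sets kept their sign under quantile normalization and with equal medians. The other alternatives could not turn a sign, because all 68 had moved the same way in all 3 calves. Of the calls, 51 of 54 under quantile normalization, 55 of 58 with equal medians and 68 of 75 with the filter at the median were shared with the 68. The count was 20 without the filter, 44 with robust variances, 0 without the intensity trend, 0 without the replicate block and 0 with the calf as a random block (limma, 1214, 639 and 1361 probe sets at an unadjusted p under 0.05), and between 100 and 139 when 1 calf was left out, with 1 residual degree of freedom and more false calls on simulated data. For gene lists 6 of 23 passed, against 1 without the replicate block and 0 with an estimated correlation. With the filter at the median 3 of 20 passed, because lists left with fewer than 5 measured genes were not tested, so that count covers fewer lists. For the response difference the count of 65 became 28 under quantile normalization, 17 with equal medians, 1 without the filter, 0 without the intensity trend (948) and 0 with the prior variance of the MDP comparison (1030). For calf 129 against the others the count of 15 became 8 under quantile normalization, 100 with equal medians, 2 without the intensity trend and 0 on the MDP arrays alone (960), and the 2 lists became 1, 4 and, on the MDP arrays alone, 0. Leaving out calf 150 or 151 there leaves no residual degree of freedom and no test. The cause of these shifts was not tested. Without detection calls, dim probe sets have no stated background, which limits what the low signals of IFNG or BOLA-DQB1 show.

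Signs turned for 1 list past the threshold, the ribosomal proteins between calves (0.0014 under quantile normalization), and otherwise for lists and genes that had not passed. For MDP against PBS the cytotoxic list had 0.065 with the smaller pseudocount, 0.0033 with equal medians and 0.013 with the mean of probe sets, homing and adhesion 0.061 with the smaller pseudocount and 0.0039 without the filter, the erythrocyte list 0.0069 with the larger pseudocount, ribosomal proteins 0.00819 under quantile normalization, and interferon response 0.0039 with the larger pseudocount, 0.0081 with equal medians and 0.011 with the filter at the median. Between calves the interferon list had 0.012 with equal medians, 0.027 with the filter at the median and 0.015 on the PBS arrays, the NOD list 0.0081 with equal medians and 0.051 on the MDP arrays, and T cell activation -0.0075 with the smaller pseudocount and -0.17 on the PBS arrays. On the PBS arrays alone cytokines had -0.082 (0.13 over all arrays), γδ markers 0.047 (-0.20 over all arrays), heat shock genes -0.0054 and NF-κB targets -0.19, and on the MDP arrays cell cycle genes -0.094 and glycolysis 0.0046. With 1 calf left out, lists ranged from -0.024 to 0.15 (chemokines), -0.12 to 0.072 (cytotoxic), -0.021 to 0.075 (glycolysis), -0.013 to 0.051 (heat shock), -0.17 to 0.095 (homing), -0.037 to 0.014 (interferon) and -0.083 to 0.018 (ribosomal proteins). Genes ranged from -0.22 to 0.14 (CCL4), -0.47 to 0.026 (CD79A), -0.17 to 0.029 (CXCL5), -0.21 to 0.065 (CXCL8), -0.91 to 0.28 (HBB), -0.073 to 0.43 (IL1B), -0.37 to 0.031 (S100A8) and -0.88 to 0.23 (ZBTB16).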

Other observations

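The tests in this part were chosen after the values were seen. Transcripts known from myeloid cells lay further apart between the calves than between PBS and MDP. S100A8 had signals of 2400 and 2319 in calf 129 (PBS and MDP), 555 and 323 in calf 150, and 10919 and 11788 in calf 151. MMP9, S100A12 and CXCL8 had the same order of calves, with CXCL8 at 11909 and 14117, 3897 and 3156, and 21746 and 20085. CD3E, in contrast, lay between 12721 and 16619 on all 6 arrays.

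Over the 20 measured monocyte and neutrophil markers, calf 151 lay on average 1.29 above calf 150 on the log2 scale, with a median over markers of 0.92. Calf 129 was at -0.25 relative to the mean of both. Neutrophil markers had means of 9.37, 8.30 and 10.6 in calves 129, 150 and 151. Monocyte and macrophage markers lay closer together, at 8.26, 8.23 and 8.96. The sort method as the whole cause is argued against, since the difference of 1.29 lies between the 2 calves sorted by the same method. That 15 of 20 markers were higher in calf 151 than in calf 150 restates the difference and does not decide whether more myeloid cells were carried over, which stays open. Both calves were sorted with magnetic beads by the γδ T cell receptor, and the labels give a purity above 98 percent for them. How many myeloid cells remained was not measured here. Expression of these genes by the T cells themselves was not tested and stays open too.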
